A study of Homo sapiens with 12 samples.

How the data were processed

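RNA from 12 libraries of monocytes sorted from the blood of healthy people was sequenced, in 4 groups of 3 libraries. Per the labels, the groups are Int, Slanneg_N, SlanposCD61_N and SlanposCD61neg_N. Int was read here as intermediate and the suffix N as nonclassical, the cell types that the extraction protocol in the labels names. Slan is a carbohydrate carried on the cell surface of many nonclassical monocytes, and CD61 is the integrin beta chain encoded by ITGB3. The label SlanposCD61_N gives no sign for CD61, and the name is used as given. Replicate numbers follow the order of the samples and were not used as pairs, because the labels give no donor, batch or date. Whether libraries of one number share a donor or a batch is not given in the sources used here, and the tests took no account of it. Nothing in the labels says that the libraries of a group came from separate donors, so p-values measure only the spread between these samples, which may be technical.

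The authors deposited a table of read counts per gene, whole numbers that were not normalised, with Entrez gene identifiers. Per the labels, libraries were made with the Universal Plus mRNA-Seq kit. Per the submitters' processing notes, FastQC 0.11.7, featureCounts 1.22.2 and edgeR 1.30.5 were used with the genome build hg38. The aligner, the gene annotation and the strand setting are not given in the sources used here. Of the 28395 identifiers in the deposited count table, 27745 were matched to a gene symbol in the RefSeq gene table of the GRCh38.p14 assembly and 650 were not. The unmatched identifiers held between 0.0474% and 0.207% of a library's counts and stayed in the library totals. Gene coordinates were taken from the same RefSeq table, whose assembly is the build named in the notes. No row of the table held a total or unassigned reads.

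Differential expression was computed from the deposited counts in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by the trimmed mean of M values (TMM), and genes of low count were removed with filterByExpr by group, which left 14378 genes, 12643 of them protein coding. One quasi-likelihood model was fitted to the 4 groups (8 residual degrees of freedom), with no covariate. Tests were two-sided F tests, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 3 main comparisons set Int against the mean of the 3 nonclassical groups, Slanneg_N against the mean of both slan-positive groups, and SlanposCD61_N against SlanposCD61neg_N. A further 5 comparisons between pairs of groups and 1 test of any difference among the 4 groups came from the same model. CPM, the counts scaled to a common library total, were computed with TMM-scaled library sizes. The summed CPM of olfactory receptor genes and the shares of MALAT1 and mitochondrial transcripts took library totals without TMM scaling. Errors are standard deviations (SD) over 3 libraries, unless another n is given, or standard errors (SE) of the model. Fold changes are on the log2 scale.

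The tests, the groups, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Of the 26 lists 1 is not reported here, and the others were sort markers, classical monocyte genes, nonclassical monocyte genes, intermediate monocyte genes, MHC class II presentation, platelet and megakaryocyte markers, NK cell markers, T cell markers, B cell markers, neutrophil markers, dendritic cell markers, erythroid markers, interferon-stimulated genes, inflammatory cytokine and chemokine genes, immediate early and stress genes, chemoattractant receptors, integrins and adhesion, complement, scavenger and efferocytosis, cholesterol and lipid handling, Fc and LILR receptors, proliferation, slan epitope synthesis, mitochondrial genome transcripts, and cytosolic ribosomal proteins. Some genes stand in several lists. Lists were tested with camera in limma 3.58.1, with a correlation between genes preset at 0.01 and again with an estimated correlation, and p-values were adjusted over the 26 lists within a comparison. Camera asks whether the genes of a list rank higher or lower than other genes. Fry, run beside it, tests whether a list moves one way on balance or, in its mixed form, whether its genes change in either direction, and compares the list with no other genes. A list score per library was the mean of log2 CPM (prior count 2), centred over the libraries, and was compared with an exact permutation test, two-sided. The smallest p such a test can give is 0.00455 for 3 libraries against 9, 0.0119 for 3 against 6, and 0.1 for 3 against 3.

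Genes were named by rule. For each main comparison, the rule took up to 12 genes per direction with the largest fold change among those with an adjusted p under 0.05, a log2 fold change of at least 1, a mean of at least 5 CPM on the higher side, and no overlap between the libraries of both sides. Where no gene qualified, it took the 5 genes with the smallest p in each direction, named as not past the test. It also took every sort marker and up to 4 members of smallest p of each list described. Genes outside the rule that are named below were chosen after their values were seen, and this is said beside them. Sex-linked marker genes, immunoglobulin and T cell receptor segments, genes whose presence differs between people and names without a symbol were left out of the naming rule.

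The position of Slanneg_N between Int and the slan-positive groups was the slope through 0 of the difference Slanneg_N minus slan-positive on the difference Int minus slan-positive. Genes were chosen, and the second difference measured, in libraries other than those against which Slanneg_N was set, for each of the 3 left-out choices in turn. A position of 0 lies at the slan-positive mean and 1 at Int.

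Alternatives fixed in advance were relative log expression scaling, no filter on low counts, a stricter filter (CPM of at least 1 in at least 6 libraries), DESeq2 1.42.0, limma voom with quality weights, robust quasi-likelihood, counts thinned at random to the smallest library total of 3793971, 1 or 2 surrogate variables from sva 3.50.0, only the libraries of the groups compared, leaving out each library in turn, an estimated correlation for camera, a prior count of 0.5 for list scores, and other gene choices for the position. Runs that left out libraries or thinned the counts applied the low-count filter anew, so the genes they tested differ from those of the main fit. An additional 4 alternatives were chosen after seeing the data. They took the replicate number as a block, left out the 4 libraries with the highest summed CPM of olfactory receptor genes, added the log2 of that CPM as a covariate, or removed a spline of transcript length and GC content (4 degrees of freedom) per library as an offset. Length and GC content were known for 13808 of the tested genes (96.0%).

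The gene and list steps were tested on simulated counts with 200 changed genes of known fold among 14378. The position step was tested on separate simulated counts, with more changed genes and with fold changes drawn from a normal distribution. Counts were drawn independently for each gene and library. These runs therefore do not show how the tests behave with correlations between genes or libraries such as the real data hold. For Int against the nonclassical groups, edgeR recovered 5.97% of genes changed 1.5-fold, 32.8% of those changed 2-fold and 68.2% of those changed 4-fold. For Slanneg_N against the slan-positive groups the shares were 4.48%, 40.3% and 74.2%. For SlanposCD61_N against SlanposCD61neg_N they were 2.99%, 26.9% and 63.6%. In these simulations edgeR called 1, 3 and 3 unchanged genes among 74, 84 and 66 calls. DESeq2 called 23, 37 and 27 among 122, 134 and 109, and limma voom 6, 2 and 1 among 78, 77 and 61. DESeq2 thus exceeded the 0.05 share of false calls. With no simulated change, edgeR called 0 genes in each comparison, with 687 to 734 at an unadjusted p under 0.05 in the main comparisons, and other tools were not run on that simulation. A 2-fold rise simulated in 24 or 26 of the 26 tested platelet genes was returned by camera as higher in the 3 main comparisons, with median log2 fold changes of 1.05, 1.01 and 1.00. Positions simulated at 0, 0.2 and 0.5 were returned as 0.005, 0.175 and 0.428, so the measure is pulled towards 0.

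Libraries of one group were checked for double deposition and differed by far more than sampling noise, with a chi-square per degree of freedom between 12.2 and 39.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genotypes and other sequence-level features were not analysed here.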

Results

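Libraries of sorted human blood monocytes were compared in 4 groups of 3, Int, Slanneg_N, SlanposCD61_N and SlanposCD61neg_N. Library totals ran from 3793971 counts (SlanposCD61_N replicate 3) to 9275359 (SlanposCD61_N replicate 2), and 17244 to 24506 genes were detected per library. The first 4 principal components of log2 CPM held 46.1%, 20.2%, 10.7% and 5.63% of the variance. Olfactory receptor genes, whose transcripts are known mainly from the nose, summed over 370 genes to 521 CPM in SlanposCD61_N replicate 3, 110 in Slanneg_N replicate 2, 99.9 in Int replicate 3 and 88.6 in SlanposCD61neg_N replicate 2, and to 50 CPM or less in the other 8 libraries. In the MHC region of chromosome 6, 127 of 166 protein-coding genes (76.5%) had under 10 counts over all libraries, against 1478 of 19009 elsewhere (7.78%). HLA-DRA had 22 counts over all libraries and CD74, which pairs with its protein but lies on another chromosome, had 421214. TNF, PSMB9, CCL3 and CCL4 had 0 counts and LILRB3 had 72, so HLA, LILR, TNF and these chemokine genes were not interpreted. On GRCh38, CD14 (Entrez 929) lies on chromosome 5 at 140631732 to 140633701 and FCGR3A (2214) on chromosome 1 at 161541759 to 161550737. CHST2 (9435) lies on chromosome 3 at 143119771 to 143124014 and ITGB3 (3690) on chromosome 17 at 47253827 to 47313743. RNASE6 (6039) lies on chromosome 14 at 20781070 to 20782467 and SCART1 (619207) on chromosome 10 at 133453945 to 133469760.

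Int cells carried far more CD14 transcript than the nonclassical groups. CD14, the lipopolysaccharide co-receptor, was 345 ± 89.5 CPM in Int (SD, n = 3), against 21.4 ± 4.04 in Slanneg_N, 24.3 ± 3.90 in SlanposCD61_N and 14.6 ± 5.85 in SlanposCD61neg_N (SD, n = 3 each). FCGR3A, which encodes CD16, was 1008 ± 226 CPM in Int and 2301 ± 184, 2042 ± 361 and 2273 ± 199 in the nonclassical groups (SD, n = 3 each), and the near-identical FCGR3B may share its reads. CHST2, a carbohydrate sulfotransferase gene, was 108 ± 24.5 CPM in Int and 272 ± 57.4, 280 ± 28.3 and 292 ± 58.1 in the nonclassical groups, in the same order (SD, n = 3 each). In the edgeR test of Int against the mean of the nonclassical groups, log2 fold changes were 4.13 for CD14 (SE 0.20, adjusted p = 9.51e-07), -1.13 for FCGR3A (SE 0.16, adjusted p = 0.000842) and -1.38 for CHST2 (SE 0.18, adjusted p = 0.000465). Values in brackets before a p, or alone after a gene, are log2 fold changes. CCR2, the receptor of the chemokine CCL2, was higher in Int (5.12, adjusted p = 0.000405), as were CD33 (0.89, adjusted p = 0.00159), B4GALT1 (0.73, adjusted p = 0.00366) and FUT7 (3.74, adjusted p = 0.00394). B4GALT1 was not called with the length and GC offset (0.80, adjusted p = 0.0590), nor was FUT7 without Int replicate 2 (3.58, adjusted p = 0.0533) or with DESeq2, which gave it no adjusted p. CX3CR1 (-0.58, adjusted p = 0.324), ITGB3 (1.33, adjusted p = 0.188), ITGA2B (1.24, adjusted p = 0.294), SELPLG (-0.28, adjusted p = 0.264) and GCNT1 (-0.19, adjusted p = 0.624) did not pass the test. CX3CR1 was called with the background covariate (-0.78, adjusted p = 0.0372) and the replicate number as a block (-0.60, adjusted p = 0.00335), and ITGB3 with the covariate (1.72, adjusted p = 0.0334) and 1 surrogate variable (1.74, adjusted p = 0.0369). Of the 12 sort markers 5 were higher and 2 lower, over all genes and adjusted over the list alone. The list ranked higher with camera (median 0.81, adjusted p = 0.00885; adjusted p = 0.0890 with an estimated correlation, and adjusted p = 0.234 with limma voom). Its name does not mean that cells were sorted on each gene, since the group labels name only slan and CD61. Where cells were sorted on a marker, a difference in it may follow from the sort.

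RNASE6, LGALS2 and CD163 were among the 12 genes with the largest rises in Int that the naming rule took. RNASE6, a secreted ribonuclease gene, was 54.6 ± 18.6 CPM in Int and 0.84 ± 0.36, 1.24 ± 0.41 and 0.50 ± 0.49 in Slanneg_N, SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each; 6.10, adjusted p = 1.81e-06). The galectin gene LGALS2 was 152 ± 55.8 CPM in Int and 5.18 ± 5.07, 3.35 ± 2.38 and 1.32 ± 1.05 in those groups (SD, n = 3 each; 5.82, adjusted p = 2.08e-05). CD163, the haemoglobin-haptoglobin receptor gene, was 78.1 ± 20.1 CPM in Int and 1.88 ± 0.84, 3.81 ± 1.75 and 1.68 ± 1.65 there (SD, n = 3 each; 5.09, adjusted p = 6.22e-06). CLEC4E (5.79), STAB1 (5.54), CLEC10A (5.45), FPR3 (4.86), PLA2G7 (4.86), ASGR2 (4.52), CD1C (4.30) and CDC42EP1 (4.19) completed, with CCR2, the 12 genes taken by the naming rule.

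SCART1, CHD5 and P2RY10 were among the genes lower in Int than in every nonclassical group. SCART1, of the scavenger receptor cysteine-rich family, was 1.41 ± 0.69 CPM in Int and 11.2 ± 0.40, 31.6 ± 3.87 and 30.4 ± 5.49 in Slanneg_N, SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each; -3.95, adjusted p = 5.90e-06). The chromatin remodeller gene CHD5 was 1.70 ± 0.96 CPM in Int and 13.6 ± 1.66, 28.4 ± 5.34 and 25.9 ± 2.08 there (SD, n = 3 each; -3.65, adjusted p = 2.08e-05). P2RY10, a receptor gene of the P2Y-like family, was 3.81 ± 2.11 CPM in Int and 28.5 ± 1.85, 38.9 ± 5.39 and 38.65 ± 4.37 there (SD, n = 3 each; -3.19, adjusted p = 2.08e-05). FBLN1 (-4.33), SYTL5 (-3.94), FIBCD1 (-3.76), CFAP57 (-3.38), VMO1 (-2.99), L1TD1 (-2.86), HMGA2-AS1 (-2.77), the creatine kinase gene CKB (-2.72) and PPM1N (-2.60) were also lower in Int. The strand setting is not given in the sources used here, so reads of HMGA2-AS1 may belong to the gene it overlaps. SYTL5 was not called with limma voom (adjusted p = 0.0732). CFAP57 was not called with limma voom (adjusted p = 0.1), without Int replicate 1 (-2.94, adjusted p = 0.0519) or without Int replicate 2 (-3.09, adjusted p = 0.0664), and VMO1 not without Int replicate 2 (-2.63, adjusted p = 0.0545).

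**Figure D1:**
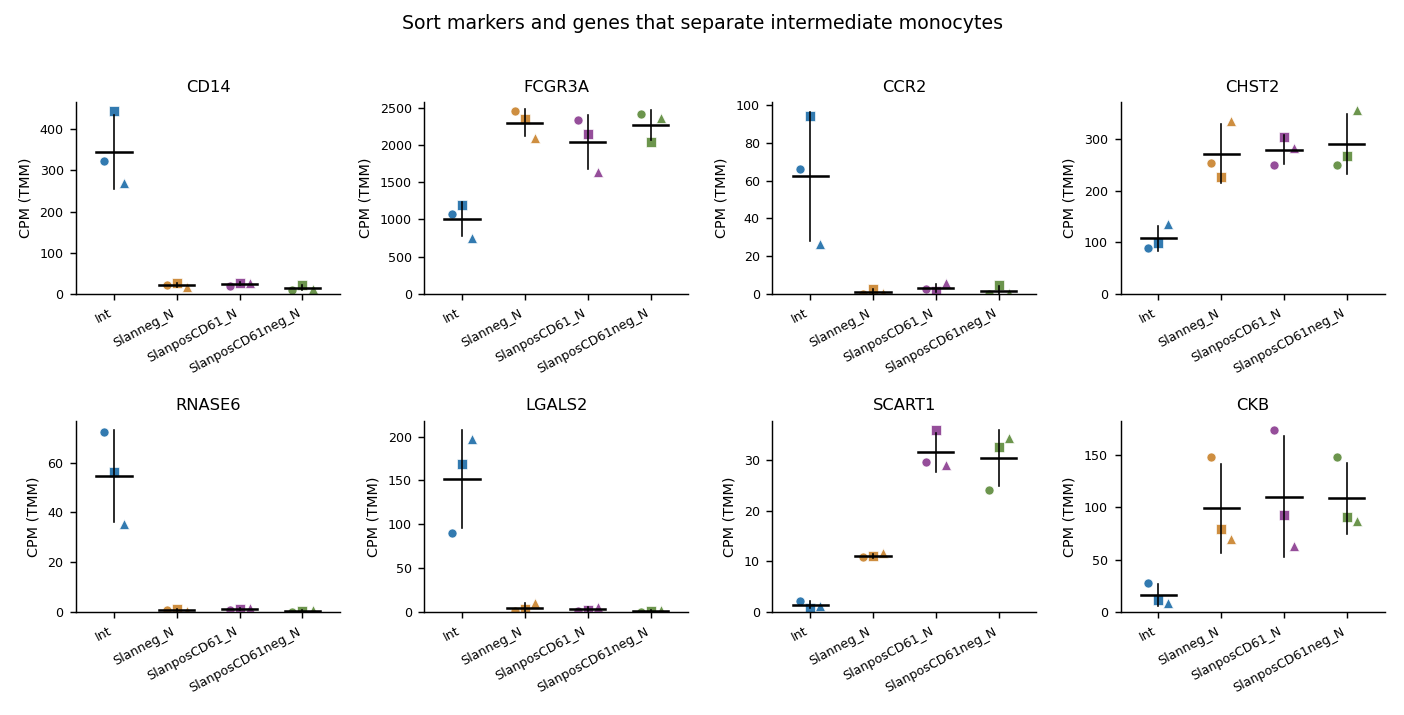
CPM (TMM-scaled) of CD14, FCGR3A, CCR2, CHST2, RNASE6, LGALS2, SCART1 and CKB per library, coloured by group and shaped by replicate number, with the mean and SD of 3 libraries as lines. CD14 was 269 CPM or more in every Int library and 27.5 CPM or less in every nonclassical library.

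Classical monocyte genes were higher in Int almost throughout. ITGAM, the CD11b gene, was 294 ± 30.9 CPM in Int and 61.7 ± 11.9, 31.3 ± 4.78 and 28.4 ± 6.94 in Slanneg_N, SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each; 2.95, adjusted p = 9.51e-07). CSF3R, the receptor gene of granulocyte colony-stimulating factor, was 277 ± 46.1 CPM in Int and 60.9 ± 3, 50.7 ± 8.19 and 38.1 ± 10 there (SD, n = 3 each; 2.50, adjusted p = 2.25e-06). TCF7L2, a transcription factor gene of the nonclassical list, was 336 ± 12 CPM in Int and 681 ± 128, 712 ± 98.6 and 771 ± 103.3 there (SD, n = 3 each; -1.10, adjusted p = 0.000438), and MS4A7 (-1.16, adjusted p = 0.000621) and SH2D1B (-2.14, adjusted p = 0.000504) were lower with it. Of 29 classical monocyte genes 26 were higher, with 27 higher and 1 lower (VNN2, -0.61) adjusted over the list alone. Their median was 2.86 (camera adjusted p = 3.75e-68; adjusted p = 0.00143 with an estimated correlation). Among 33 nonclassical monocyte genes 14 were lower, with 16 lower and 1 higher (IFITM3) adjusted over the list alone. Their median was -0.59 (camera adjusted p = 1.73e-11; adjusted p = 0.0890 with an estimated correlation). All 11 intermediate monocyte genes that passed, of 14 over all genes or adjusted over the list alone, were higher (median 2.25, camera adjusted p = 2.57e-12; adjusted p = 0.0383 with an estimated correlation), among them MARCO (2.82) and ZNF385A (1.60). List scores, in centred log2 CPM, were 2.26 ± 0.26 in Int (SD, n = 3) and -0.75 ± 0.48 in the nonclassical libraries (SD, n = 9) for the classical genes, and -0.64 ± 0.22 and 0.21 ± 0.22 for the nonclassical genes. The exact permutation p of both, and of the intermediate genes (1.92 ± 0.23 and -0.64 ± 0.79), was 0.00455, the smallest that 3 libraries against 9 can give (exact adjusted p = 0.00985).

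CD74 and CD36 were among the antigen presentation and scavenging genes higher in Int. CD74, the invariant chain of MHC class II, was 10271 ± 2196 CPM in Int and 4162 ± 917, 2828 ± 233 and 2810 ± 496 in Slanneg_N, SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each; 1.68, adjusted p = 4.71e-05). IFI30 (0.99), CTSH (1.38) and CIITA (0.94), the class II transactivator gene, were higher as well. Of the 17 genes of MHC class II presentation only 10 could be tested, only HLA-DRB1 of them an HLA gene, and 5 were higher, or 6 adjusted over the list alone. Their median was 0.96 (camera adjusted p = 1.84e-06; adjusted p = 0.0149 with an estimated correlation). CD36, a receptor of oxidised lipoprotein, was 228 ± 56.4 CPM in Int and 41.1 ± 21.6, 30.0 ± 22.3 and 24.5 ± 15.5 there (SD, n = 3 each; 2.86, adjusted p = 0.000738). Among 23 scavenger and efferocytosis genes 10 were higher, or 11 adjusted over the list alone. Their median was 0.60 (camera adjusted p = 1.14e-08; adjusted p = 0.0149 with an estimated correlation). In cholesterol and lipid handling, the liver X receptor gene NR1H3 (1.70) was higher and INSIG1 (-0.94), a sterol feedback gene, was lower. Of its 26 genes 7 were higher and 2 lower, or 11 and 4 adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.00939; adjusted p = 0.0470 with an estimated correlation).

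The immediate early genes FOS, JUN and FOSB were higher in Int, and ATF3 was lower. FOS was 762 ± 75.1 CPM in Int and 81.4 ± 21.1, 83.0 ± 24.2 and 58.5 ± 25.7 in Slanneg_N, SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each; 3.38, adjusted p = 9.56e-06). JUN was 74.1 ± 12.2 CPM in Int and 9.32 ± 0.66, 9.72 ± 1.17 and 7.81 ± 2.66 there (SD, n = 3 each; 3.05, adjusted p = 1.11e-06), FOSB stood at 2.74 and ATF3 at -1.02 (adjusted p = 0.000413). Of 26 immediate early and stress genes 12 were higher and 1 lower, or 14 and 1 adjusted over the list alone. Their median was 0.64 (camera adjusted p = 2.00e-09; adjusted p = 0.0474 with an estimated correlation). VEGFA (3.95), PTGS2 (1.90), IL1RN (1.49) and TNFSF13B (0.95) were higher among the 17 inflammatory cytokine and chemokine genes, 7 of which were higher over all genes or adjusted over the list alone. Their median was 0.95 (camera adjusted p = 5.88e-06; adjusted p = 0.0149 with an estimated correlation). Of 28 interferon-stimulated genes 2 were higher, over all genes or adjusted over the list alone. The list was not called (median 0.12, camera adjusted p = 0.191; adjusted p = 0.843 with an estimated correlation; exact adjusted p = 0.495 for the list score). Without Int replicate 3 (0.43, adjusted p = 0.000263) or SlanposCD61_N replicate 2 (0.24, adjusted p = 0.0257) the list was called by camera. It was also called with no filter (adjusted p = 0.0121), DESeq2 (adjusted p = 0.0161), 2 surrogate variables (adjusted p = 5.14e-07) and without the 4 libraries of highest olfactory receptor CPM (adjusted p = 0.000308). The replicate number as a block gave a call too, although the labels give no pairing. All these calls took the preset correlation of 0.01, while the main fit estimated 0.82 for this list, so their p-values overstate the evidence. The list score of each Int library lay above those of all nonclassical libraries of its own number (0.414, 0.89 and -0.512 against at most 0.158, 0.432 and -0.709).

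Complement genes and chemoattractant receptors held both higher and lower genes. Against the nonclassical mean, the C1q genes C1QA, C1QB (1.58) and C1QC (2.04), SERPING1 (1.92), VSIG4 (2.31) and CFP (1.16) were higher in Int. C3 (-2.43) and C5AR2 (-1.65) were lower. C1QA was 36.51, 109.95 and 57.2 CPM in the Int libraries and 44.83, 66.85 and 51.71 CPM in Slanneg_N, so these groups overlapped. It was 14.53 to 26.65 CPM in the slan-positive libraries. Complement genes held 7 higher and 2 lower of 18, over all genes or adjusted over the list alone. Their median was 0.01 (camera adjusted p = 0.00540; adjusted p = 0.0417 with an estimated correlation; adjusted p = 0.0865 with limma voom). The complement list was also not called with the replicate number as a block. Chemoattractant receptors, with CCR2, FPR3 and PTAFR (1.85) higher, held 9 higher and 2 lower of 25, over all genes or adjusted over the list alone. Their median was 0.79 (camera adjusted p = 0.0244; adjusted p = 0.323 with an estimated correlation; adjusted p = 0.0543 with limma voom). The list was not called without Int replicate 1 (0.26, adjusted p = 0.0854), without Int replicate 2 (0.18, adjusted p = 0.0973) or without SlanposCD61neg_N replicate 3 (0.22, adjusted p = 0.0510). Among 31 genes of integrins and adhesion, CD63 (2.10) and JAML (1.31) were higher, with 8 higher and 3 lower in all, or 9 and 4 adjusted over the list alone. Their median was 0.08 (camera adjusted p = 0.000342; adjusted p = 0.0417 with an estimated correlation; adjusted p = 0.0588 with limma voom). SIRPA (2.54), TREM1 (2.37), SIGLEC7 (1.61) and FCGRT (1.45) were higher and SIGLEC10 (-0.87) lower among 24 Fc and LILR receptors, which held 7 higher and 2 lower, or 9 and 2 adjusted over the list alone. Their median was 0.30 (camera adjusted p = 0.00190; adjusted p = 0.193 with an estimated correlation).

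RPLP1 and 21 other ribosomal protein genes were higher in Int. RPLP1 was 1084 ± 87.5 CPM in Int and 581 ± 43.0, 403 ± 57.6 and 426 ± 57.5 in Slanneg_N, SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each; 1.23, adjusted p = 3.98e-05). Of 35 cytosolic ribosomal proteins 22 were higher, or 28 adjusted over the list alone. Their median was 0.70 (camera adjusted p = 5.35e-16; adjusted p = 0.174 with an estimated correlation; exact adjusted p = 0.00985 for the list score). Fold changes fell with transcript length in this comparison (Spearman correlation -0.32 across genes), and with the length and GC offset the ribosomal median was 0.57 (adjusted p = 2.09e-09). Among 12 mitochondrial genome transcripts only ND3 was higher (0.93), over all genes or adjusted over the list alone, and not with the length and GC offset (0.63, adjusted p = 0.135). The mitochondrial list (median 0.30, camera adjusted p = 0.0344; adjusted p = 0.644 with an estimated correlation) was not called without Int replicate 3 (0.16, adjusted p = 0.274), without SlanposCD61_N replicate 3 (0.25, adjusted p = 0.0829), without SlanposCD61neg_N replicate 2 (0.28, adjusted p = 0.0551), or with the stricter filter (adjusted p = 0.0521), limma voom (adjusted p = 0.234), thinned counts (adjusted p = 0.0558), 1 or 2 surrogate variables (adjusted p = 0.129 and adjusted p = 0.354), the background covariate (adjusted p = 0.0735) or the length and GC offset (adjusted p = 0.746). Without the 4 libraries of highest olfactory receptor CPM camera ranked it lower (median 0.01, adjusted p = 0.889). Of 17 genes of slan epitope synthesis 5 were higher and 3 lower, over all genes or adjusted over the list alone, with no call by camera (median 0.05, adjusted p = 0.634), while fry in its mixed form gave an adjusted p of 1.02e-08. Proliferation genes held 2 higher of 15, over all genes or adjusted over the list alone (median -0.001, mean 0.04, ranked higher with camera adjusted p = 0.697).

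Markers of other cell types were measured in the same libraries. PPBP, a platelet chemokine gene, was 16.9 ± 13.9 CPM in Int, 0.94 ± 0.66 in Slanneg_N, 14.5 ± 10.01 in SlanposCD61_N and 1.35 ± 0.95 in SlanposCD61neg_N (SD, n = 3 each; 2.66, adjusted p = 0.0141; adjusted p = 0.115 without Int replicate 1; adjusted p = 0.0979 with limma voom). Platelet and megakaryocyte markers, 26 of 41 tested, held 6 higher, or 7 adjusted over the list alone. Their median was 0.92 (camera adjusted p = 0.00939; adjusted p = 0.580 with an estimated correlation; adjusted p = 0.0558 with thinned counts; 0.30 and adjusted p = 0.390 without Int replicate 1; exact p = 0.273 for the list score). GNLY, a cytotoxic granule gene, was 18.3 ± 11.2 CPM in Int and 3.33 ± 1, 7.95 ± 2.71 and 2.79 ± 1.98 in the nonclassical groups (SD, n = 3 each; 2.13, adjusted p = 0.00339). NK cell markers held 3 higher and 1 lower of 18, over all genes or adjusted over the list alone. Their median was 1.33 (camera adjusted p = 0.0437; adjusted p = 0.681 with an estimated correlation; adjusted p = 0.0646 with the stricter filter; adjusted p = 0.0916 with thinned counts). That call ended without Slanneg_N replicate 2 (1.37, adjusted p = 0.0663) or without SlanposCD61neg_N replicate 1 (1.16, adjusted p = 0.112), and without Int replicate 1 camera ranked the list lower (median 0.23, adjusted p = 0.835). Dendritic cell markers held 2 higher of 12, over all genes or adjusted over the list alone. Their median was 1.06 (camera adjusted p = 0.00763; adjusted p = 0.193 with an estimated correlation). T cell markers held 0 of 18 (median -1.08, camera adjusted p = 0.268), erythroid markers 0 of 6 (0.92, adjusted p = 0.697) and neutrophil markers 1 lower of 9 over all genes and 0 adjusted over the list alone (0.55, adjusted p = 0.776). B cell markers held 2 lower of 13 over all genes or adjusted over the list alone (-0.84, camera adjusted p = 0.178, but adjusted p = 0.0434 without Int replicate 2).

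Between Int and the mean of the nonclassical groups 2492 of 14378 genes passed the edgeR test, 1508 higher and 984 lower in Int, 817 of them changed 2-fold or more, and 4359 had an unadjusted p under 0.05 where 719 would be met by chance. With no filter on low counts 1557 genes passed, with the length and GC offset 1200 and with 2 surrogate variables 4022. Without Int replicate 1 the count was 1783 (1392 higher and 391 lower), without Int replicate 2 it was 1157 (913 and 244) and without Int replicate 3 it was 1652 (1160 and 492). In these single omissions the low-count filter was applied anew, and 16088, 16105 and 15994 genes were tested. With all libraries and no filter, 1079 genes were higher and 478 lower. The change in balance therefore cannot be assigned to the single libraries. CD14, RNASE6, CD163, SCART1 and CHD5 passed in every alternative run in which they were tested, as did 68 of the 89 named genes that passed. Some named genes were not tested in some runs.

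**Figure D2:**
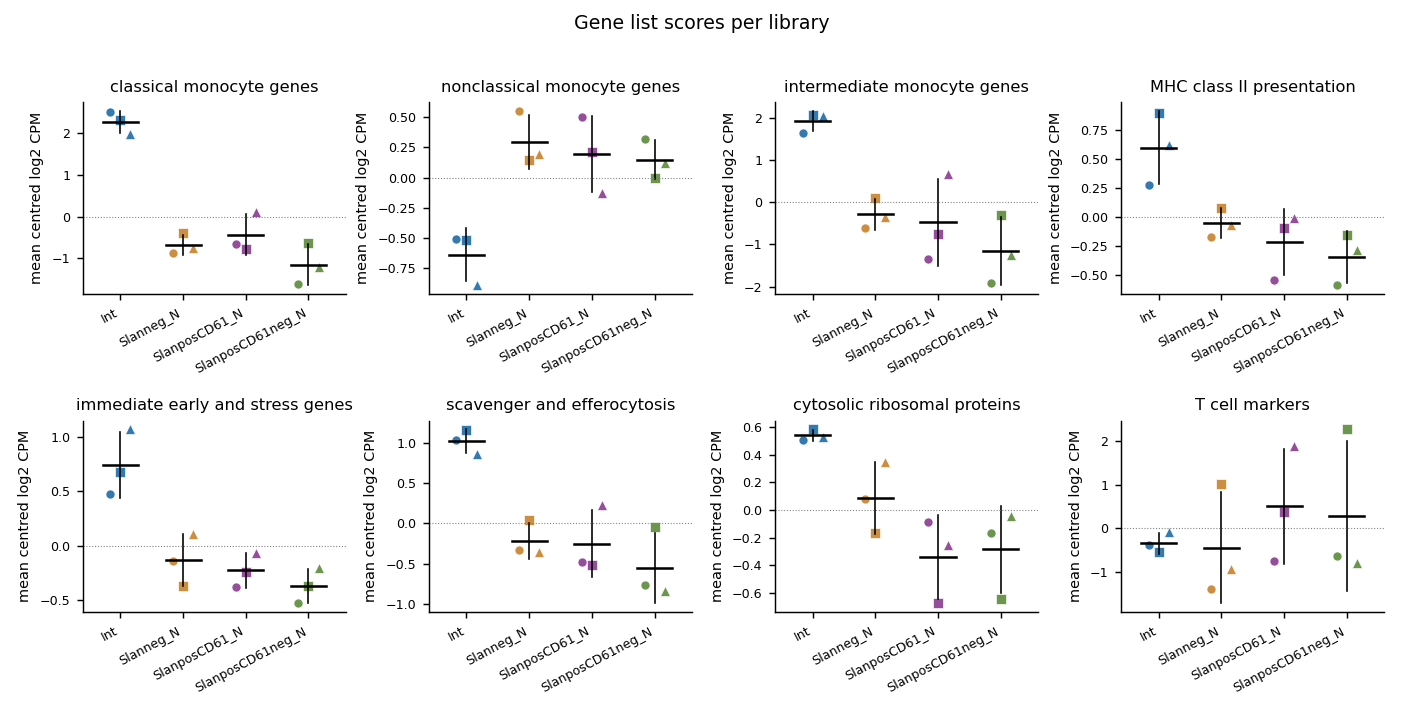
Mean centred log2 CPM of the classical, nonclassical, intermediate, MHC class II, immediate early, scavenger, ribosomal and T cell lists per library, coloured by group and shaped by replicate number, with the mean and SD of 3 libraries as lines and a dotted line at 0. Classical genes stood at 2.26 in Int on average and at -0.75 over the nonclassical libraries.

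CHST2 and SELPLG, genes related to slan, were detected in Slanneg_N and in both slan-positive groups. CHST2 was 272 ± 57.4 CPM in Slanneg_N, 280 ± 28.3 in SlanposCD61_N and 292 ± 58.1 in SlanposCD61neg_N (SD, n = 3 each), and SELPLG, the gene of the protein that carries slan, was 1157 ± 321, 936 ± 145 and 945 ± 126 CPM (SD, n = 3 each). SCART1 was lower in Slanneg_N, at 10.8 to 11.6 CPM, than in any slan-positive library, at 24.2 to 36.1 CPM. ITGAM was 61.7 ± 11.9 CPM in Slanneg_N and 31.3 ± 4.78 and 28.4 ± 6.94 in SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each). C1QA, a C1q subunit gene, was 54.5 ± 11.3 CPM in Slanneg_N and 23.2 ± 3.63 and 16.5 ± 2.13 there (SD, n = 3 each). None of these passed the unpaired edgeR test of Slanneg_N against the mean of both slan-positive groups, with SCART1 at -1.47 (SE 0.21, adjusted p = 0.127), ITGAM at 1.05 (SE 0.17, adjusted p = 0.127), C1QA at 1.47 (SE 0.27, adjusted p = 0.142), CHST2 at -0.07 (adjusted p = 0.886) and SELPLG at 0.30 (adjusted p = 0.454). Of 17 genes of slan epitope synthesis 9 were positive and 0 passed (median 0.04, mean -0.02, ranked higher, camera adjusted p = 0.406). Also at the smallest p and not past the test were CPVL (0.65), CD63 (1.10) and CREBL2 (0.57), and in the other direction INO80D (-0.79), UBR4 (-0.67), SH3PXD2A (-1.10) and APPL2 (-0.67). CD14 (0.19, adjusted p = 0.758), FCGR3A (0.10, adjusted p = 0.820) and ITGB3 (-2.29, adjusted p = 0.285) did not pass either.

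With the unpaired edgeR test 0 genes passed between Slanneg_N and the slan-positive groups, and 1914 had an unadjusted p under 0.05 where 719 would be met by chance. DESeq2 called 255, with SCART1 (adjusted p = 8.31e-08), ITGAM (adjusted p = 2.46e-05) and C1QA (adjusted p = 0.000424) among them. In the simulation of this comparison 37 of 134 DESeq2 calls were unchanged genes. The fit with 2 surrogate variables gave 224. The replicate number as a block, although the labels give no pairing, gave 414. These held SCART1 (-1.47, adjusted p = 0.00727), C1QA (1.46, adjusted p = 0.00759) and ITGAM (1.06, adjusted p = 0.0135). The 9 genes called with limma voom were SCART1 (-1.41, adjusted p = 0.0399), UBR4 (-0.71, adjusted p = 0.0399), INO80D (-0.77, adjusted p = 0.0399), ITGAM (1.14, adjusted p = 0.0446), CPVL (0.62, adjusted p = 0.0446), KMT2C (-0.82, adjusted p = 0.0446), CHD7 (-1.05, adjusted p = 0.0446), MACF1 (-0.97, adjusted p = 0.0496) and HELZ (-0.61, adjusted p = 0.0496). With thinned counts SCART1 alone was called (-1.43, adjusted p = 0.0321), and with only the groups compared C1QA (1.47, adjusted p = 0.0291) and SCART1 (-1.47, adjusted p = 0.0291) were. KMT2C, CHD7, MACF1 and HELZ were named after their values were seen.

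Ribosomal, antigen presentation and complement lists ranked higher in Slanneg_N than in the slan-positive groups with the preset correlation. With an estimated correlation none was called (in that order, adjusted p = 0.344, adjusted p = 0.181 and adjusted p = 0.167). Of 35 cytosolic ribosomal proteins 34 had a positive fold change, and 2 passed adjusted over the list alone, RPLP1 and RPS14. The median of the list was 0.37 (camera adjusted p = 1.40e-14). CD74 was 4162 ± 917 CPM in Slanneg_N and 2828 ± 233 and 2810 ± 496 in SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each), and with IFI30 it passed adjusted over the list alone in MHC class II presentation. Over the whole list the median was 0.40 (camera adjusted p = 0.00259). In complement, C1QA, C1QB, CFP and ITGAM passed adjusted over the list alone. The median of the list was 0.13 (camera adjusted p = 0.00259; adjusted p = 0.0611 with limma voom). Fry gave MHC class II presentation and complement an adjusted p of 0.0478 each for a move to one side. ITGAM, FCN1 and PLBD1 passed adjusted over the list alone among the classical genes. The median of the list was 0.21 (camera adjusted p = 0.00139; adjusted p = 0.419 with an estimated correlation). ZNF385A passed in that way among the intermediate genes (median 0.39, camera adjusted p = 0.00202; adjusted p = 0.419 with an estimated correlation), whose call ended without Slanneg_N replicate 2 (-0.16, adjusted p = 0.0549). Platelet markers ranked lower in Slanneg_N, with 3 of 26 positive. Their median was -1.23 (camera adjusted p = 0.000591; adjusted p = 0.419 with an estimated correlation; adjusted p = 0.0611 with limma voom). The list score was -0.76 ± 0.37 in Slanneg_N, -0.65 ± 0.24 in SlanposCD61neg_N and 0.86 ± 0.96 in SlanposCD61_N (SD, n = 3 each). SlanposCD61neg_N thus stood near Slanneg_N, and the difference lay with SlanposCD61_N. Over all genes 0 members of any list passed. Fold changes in this comparison fell with transcript length (Spearman correlation -0.35 across genes), and with the length and GC offset the medians were 0.37 for cytosolic ribosomal proteins (adjusted p = 1.55e-09), 0.43 for MHC class II presentation (adjusted p = 0.0125) and 0.20 for complement (adjusted p = 0.00188).

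Further lists were called with the preset correlation, but not in every run that left out a single Slanneg_N library. Mitochondrial genome transcripts were positive for all 12 genes (median 0.28, camera adjusted p = 0.000939; adjusted p = 0.419 with an estimated correlation; adjusted p = 0.0570 without Slanneg_N replicate 1). ITGAM, CD63 and JAML passed adjusted over the list alone in integrins and adhesion (median 0.06, mean -0.07, ranked higher, camera adjusted p = 0.00620; adjusted p = 0.233 with an estimated correlation; adjusted p = 0.138 without Slanneg_N replicate 1). MSR1, C1QA and C1QB did so in scavenger and efferocytosis (0.09, adjusted p = 0.0113; adjusted p = 0.233 with an estimated correlation; adjusted p = 0.0894 without Slanneg_N replicate 2). FCGRT did among Fc and LILR receptors (0.22, adjusted p = 0.0149; adjusted p = 0.419 with an estimated correlation; adjusted p = 0.280 without Slanneg_N replicate 1; adjusted p = 0.0607 without SlanposCD61_N replicate 3), and TNFSF13B among inflammatory genes (0.26, adjusted p = 0.0263; adjusted p = 0.233 with an estimated correlation; adjusted p = 0.0578 without Slanneg_N replicate 3). Immediate early genes (0.20, adjusted p = 0.0215; adjusted p = 0.450 with an estimated correlation) were not called without Slanneg_N replicate 1 (adjusted p = 0.0521) or without Slanneg_N replicate 3 (adjusted p = 0.221). T cell markers, all 18 negative (-1.11, adjusted p = 0.0149; adjusted p = 0.704 with an estimated correlation), were not called without Slanneg_N replicate 1 (adjusted p = 0.278), without Slanneg_N replicate 3 (adjusted p = 0.0904), without SlanposCD61_N replicate 3 (adjusted p = 0.109) or without SlanposCD61neg_N replicate 2 (adjusted p = 0.398). With limma voom or surrogate variables all of these lists but scavenger and efferocytosis were also not called in at least 1 run, at adjusted p from 0.0539 (mitochondrial, limma voom) to 0.977 (T cell markers, 2 surrogate variables, where the direction turned). The length and GC offset ended the calls of mitochondrial (adjusted p = 0.313) and inflammatory genes (adjusted p = 0.0934), thinned counts (adjusted p = 0.0722) and the stricter filter (adjusted p = 0.0534) that of immediate early genes, and omission of the 4 libraries of highest olfactory receptor CPM that of Fc and LILR receptors (adjusted p = 0.170). The other 12 lists were not called, at camera adjusted p from 0.0623 (nonclassical monocyte genes, and cholesterol and lipid handling) to 0.926 (chemoattractant receptors, median 0.02, mean -0.22). Of these 12 lists 7 were called in at least 1 other run, interferon-stimulated genes among them. Nonclassical monocyte genes were called as higher with no filter (adjusted p = 0.00784), DESeq2 (adjusted p = 0.00178), only the groups compared (adjusted p = 0.0359) or the background covariate (adjusted p = 0.0317), and without any single library but Slanneg_N replicate 1, SlanposCD61_N replicate 3 and SlanposCD61neg_N replicate 2 (lowest adjusted p = 0.00355, without SlanposCD61_N replicate 1). Cholesterol and lipid handling was called as higher with no filter (adjusted p = 0.0194), DESeq2 (adjusted p = 0.00178), the length and GC offset (adjusted p = 0.0312) or without the 4 libraries of highest olfactory receptor CPM (adjusted p = 0.0437), and in 8 of the 12 single omissions (highest adjusted p = 0.0496, without SlanposCD61_N replicate 1). Calls of these 2 lists took the preset correlation. With an estimated correlation the main fit gave camera adjusted p = 0.704 for nonclassical genes and 0.233 for cholesterol and lipid handling. No list score passed, and cytosolic ribosomal proteins had an exact p of 0.107 (exact adjusted p = 0.774).

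ITGB3 and other platelet genes had higher means in SlanposCD61_N than in SlanposCD61neg_N, but none passed the edgeR test. ITGB3, the CD61 gene, was 14.3 ± 10.3 CPM in SlanposCD61_N and 1.58 ± 1.27 in SlanposCD61neg_N (SD, n = 3 each), and its platelet partner ITGA2B was 8.69 ± 6.62 and 1.10 ± 0.92 CPM (SD, n = 3 each). CAVIN2 was 15.97 ± 7.94 and 1.71 ± 0.70 CPM, TUBB1, a platelet tubulin gene, 36.4 ± 18.6 and 7.74 ± 0.79 CPM, and F13A1, which platelets and monocytes both express, 19.6 ± 15.4 and 1.90 ± 0.37 CPM (SD, n = 3 each). Int stood near SlanposCD61_N for ITGB3 (7.03 ± 5.20 CPM, SD, n = 3) and above it for F13A1 (73.8 ± 40.4 CPM, SD, n = 3). In the edgeR test log2 fold changes were 3.15 for ITGB3 (SE 0.89), 2.93 for ITGA2B, 3.20 for CAVIN2 (SE 0.65), 2.22 for TUBB1 (SE 0.55) and 3.31 for F13A1, each at an adjusted p of 0.9999. MYL9 (3.70) and CLU (2.92), and in the other direction MIR3609 (-0.94), CHMP3 (-0.59), EXOC6B (-0.35), SCARNA16 (-0.76) and MRPL44 (-0.44), were the remaining genes of smallest p, and reads of the small RNAs MIR3609 and SCARNA16 may belong to overlapping genes. CD14 (0.73), CHST2 (-0.06) and FCGR3A (-0.15) did not pass either. With edgeR 0 genes passed and 130 had an unadjusted p under 0.05 where 719 would be met by chance. Another regrouping of the same libraries gave 2324. With a count so far under chance, the 0 genes do not show that the groups are alike. Limma voom called 0, and DESeq2 called 2, F13A1 (3.35, adjusted p = 0.00289) and CAVIN2 (3.21, adjusted p = 0.0246). In the simulation of this comparison 27 of 109 DESeq2 calls were unchanged genes.

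Platelet and megakaryocyte markers had the smallest camera p between the CD61 groups (adjusted p = 1.63e-35; adjusted p = 0.0660 with an estimated correlation). Of 26 genes 25 were positive, and 10 passed adjusted over the list alone, PPBP (3.40), PF4 (3.40), ITGA2B, ITGB3, TUBB1, CLU, SPARC (2.89), MYL9, GNG11 (4.01) and CAVIN2, against 0 over all genes. The median of the list was 2.08, and 0.90 without SlanposCD61_N replicate 3. Its score was 0.86 ± 0.96 in SlanposCD61_N and -0.65 ± 0.24 in SlanposCD61neg_N (SD, n = 3 each; exact p = 0.1, the smallest possible). Fry did not call it (adjusted p = 0.488, and adjusted p = 0.275 in its mixed form). F13A1 passed adjusted over the list alone among classical genes, 25 of 29 of which were positive. Over the whole list the median was 0.73 (camera adjusted p = 4.71e-14; adjusted p = 0.113 with an estimated correlation). GNLY, at 7.95 ± 2.71 and 2.79 ± 1.98 CPM (SD, n = 3 each), stood in the NK cell markers. Over the whole list the median was 0.88 (camera adjusted p = 2.22e-07; adjusted p = 0.451 with an estimated correlation).

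**Figure D3:**
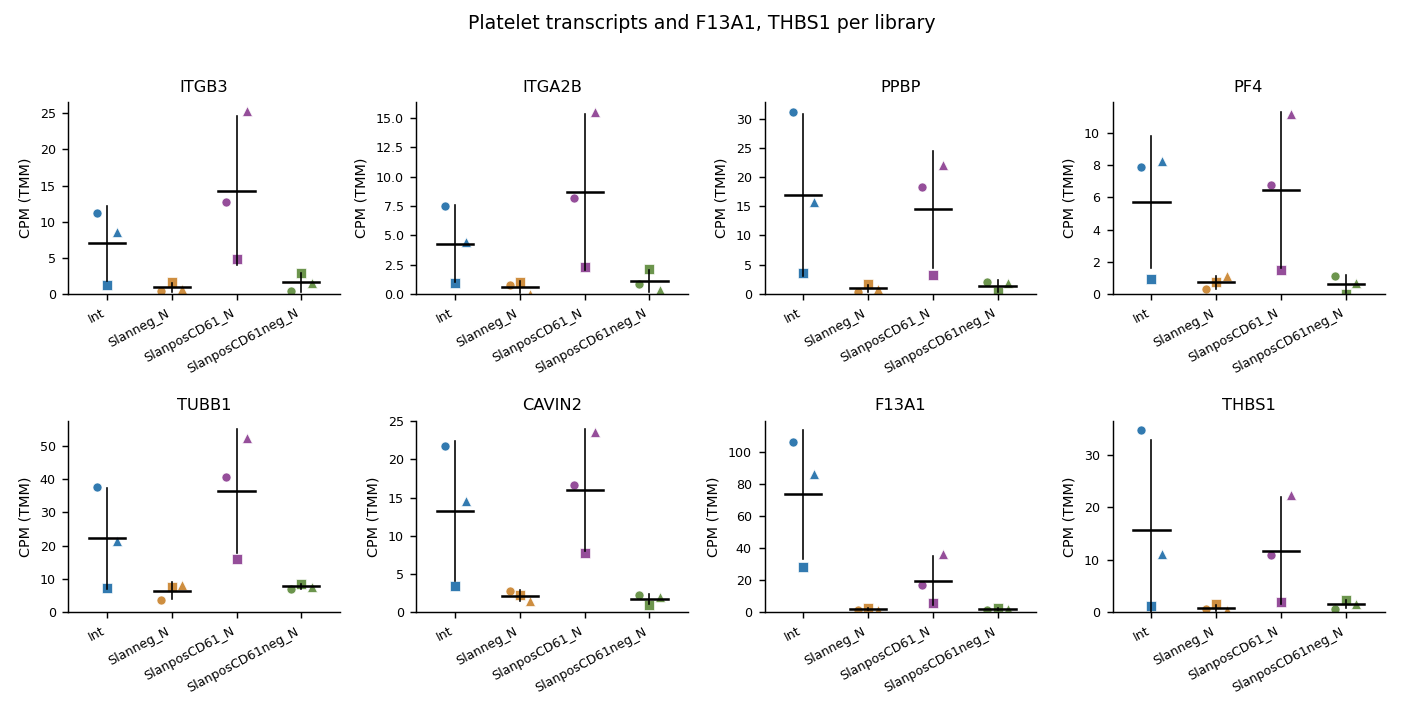
CPM (TMM-scaled) of ITGB3, ITGA2B, PPBP, PF4, TUBB1, CAVIN2, F13A1 and THBS1 per library, coloured by group and shaped by replicate number, with the mean and SD of 3 libraries as lines. ITGB3 was 12.7, 4.87 and 25.3 CPM in the SlanposCD61_N libraries and 0.38, 2.91 and 1.46 CPM in the SlanposCD61neg_N libraries.

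Intermediate, erythroid, mitochondrial and sort marker lists were called between the CD61 groups, but not in every run that left out a single library. Intermediate monocyte genes (median 0.85, camera adjusted p = 0.000282; adjusted p = 0.426 with an estimated correlation) were not called without SlanposCD61_N replicate 3 (0.10, adjusted p = 0.317) or without SlanposCD61neg_N replicate 1 (0.58, adjusted p = 0.209). All 6 erythroid markers were positive (0.95, adjusted p = 0.0374; adjusted p = 0.426 with an estimated correlation), and not called without SlanposCD61_N replicate 1 (adjusted p = 0.512), without SlanposCD61neg_N replicate 2 (adjusted p = 0.192), without SlanposCD61neg_N replicate 3 (adjusted p = 0.415) or with DESeq2 (adjusted p = 0.0722). Mitochondrial genome transcripts (0.20, adjusted p = 0.0128; adjusted p = 0.705 with an estimated correlation) were not called without SlanposCD61_N replicate 1 (adjusted p = 0.963), without SlanposCD61_N replicate 2 (adjusted p = 0.0834), without SlanposCD61neg_N replicate 2 (adjusted p = 0.573) or with DESeq2 (adjusted p = 0.212). Sort markers (median 0.01, mean 0.60, adjusted p = 0.0207; adjusted p = 0.264 with an estimated correlation) were not called without SlanposCD61_N replicate 1 (adjusted p = 0.424), without SlanposCD61_N replicate 2 (adjusted p = 0.0834), or with DESeq2 (adjusted p = 0.293) or limma voom (adjusted p = 0.0856). The other 18 lists were not called, from a camera adjusted p of 0.0536 for cytosolic ribosomal proteins (median -0.08) to 0.968 for T cell markers (median -0.15). Of these some were called in other runs and not always in 1 direction. T cell markers were called as higher without SlanposCD61_N replicate 1 (0.23, adjusted p = 0.0414) and without SlanposCD61neg_N replicate 2 (2.07, adjusted p = 2.93e-05) and as lower without SlanposCD61_N replicate 3 (-1.34, adjusted p = 0.0363) and without SlanposCD61neg_N replicate 3 (-0.51, adjusted p = 0.0310). Interferon-stimulated genes were called as higher without the 4 libraries of highest olfactory receptor CPM (0.45, adjusted p = 2.38e-08) and without SlanposCD61_N replicate 3 (0.26, adjusted p = 0.000201), and as lower without SlanposCD61_N replicate 1 (-0.10, adjusted p = 0.0370), without SlanposCD61_N replicate 2 (-0.29, adjusted p = 3.05e-05) and without SlanposCD61neg_N replicate 3 (-0.24, adjusted p = 7.67e-08). Nonclassical genes turned in the same way (-0.12, adjusted p = 0.00764 without SlanposCD61_N replicate 1, and 0.17, adjusted p = 0.000272 without SlanposCD61_N replicate 3). B cell, neutrophil, dendritic cell, immediate early, chemoattractant, integrin, scavenger and Fc receptor lists were each called in 1 to 4 runs. Cytosolic ribosomal proteins were called as lower when any of 8 single libraries was left out, at adjusted p down to 4.63e-09 (-0.23, without SlanposCD61neg_N replicate 2). They were also called with no filter (adjusted p = 0.000267), DESeq2 (adjusted p = 0.000112) or the length and GC offset (adjusted p = 0.00892). All these calls took the preset correlation of 0.01, so their p-values overstate the evidence. With an estimated correlation the main fit gave camera adjusted p = 0.879 for ribosomal, 0.894 for interferon-stimulated, and 0.991 for both T cell and nonclassical genes. Estimated correlations were 0.68, 0.82, 0.74 and 0.28 in that order.

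Fewer genes passed between Int and Slanneg_N than between Int and either slan-positive group. CPVL was 676 ± 37.9 CPM in Int, 257 ± 12.6 in Slanneg_N, and 154 ± 17.7 and 174 ± 9.86 in SlanposCD61_N and SlanposCD61neg_N (SD, n = 3 each), and FCN1, a ficolin gene, was 3760 ± 645, 1697 ± 38.4, 842 ± 346 and 835 ± 287 CPM in the same order (SD, n = 3 each). Between Int and Slanneg_N 456 genes passed (289 higher, 167 lower; 2065 at an unadjusted p under 0.05), between Int and SlanposCD61_N 2052 (1139 and 913; 4298) and between Int and SlanposCD61neg_N 2354 (1312 and 1042; 4298). Any difference among the 4 groups was called for 1497 genes (3444 at an unadjusted p under 0.05). Between Slanneg_N and SlanposCD61_N 0 genes passed with edgeR (1545 at an unadjusted p under 0.05; 87 with DESeq2, 0 with limma voom), and between Slanneg_N and SlanposCD61neg_N 0 (1421; 112 with DESeq2, 0 with limma voom, 140 with 2 surrogate variables). With the replicate number as a block, genes were called in both of these pairs, as given below. The position of Slanneg_N on the axis from the slan-positive mean to Int was 0.202 ± 0.057 (SD over the 3 left-out choices; 0.268, 0.165 and 0.174), and that of the Int libraries left out was 0.899 ± 0.132. Other gene choices gave 0.168 and 0.182. All 3 left-out choices used the same 3 Slanneg_N libraries, so the SD of 0.057 holds no spread between those libraries. Between Int and Slanneg_N the count was 292, 178 and 218 without Int replicates 1, 2 and 3, 221, 179 and 157 without Slanneg_N replicates 1, 2 and 3, and up to 1543 with 2 surrogate variables. Between Int and SlanposCD61_N it was 788 without SlanposCD61_N replicate 2, and 973 and 1364 without Int replicates 2 and 3. Between Int and SlanposCD61neg_N it was 1063 without Int replicate 2, and 1266, 1398 and 1307 without SlanposCD61neg_N replicates 1, 2 and 3. The length and GC offset left 259, 807 and 904 genes in these 3 comparisons and 600 with any difference.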

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

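The labels give no donor, batch or pairing, and the replicate numbers follow the order of the samples, which run in 3 sets with 1 library of each group. Deviations from the group means correlated at over 0.1 in 13 of the 18 pairs of libraries of one number (mean 0.28, from -0.466 to 0.741), and at -0.135 on average in the 36 other pairs across groups. All 3 pairs were over 0.1 for Int with SlanposCD61_N (0.423, 0.534 and 0.68) and for Slanneg_N with SlanposCD61neg_N (0.59, 0.741 and 0.498), and not in all pairs of groups. All 12 libraries correlated best with a library of their own number, a hint from the data and not the design that the numbers may mark a shared donor or batch. With the replicate number as a block, chosen after seeing the data, 4182 genes passed for Int against the nonclassical groups (2491 of the 2492), 414 for Slanneg_N against the slan-positive groups, 0 for SlanposCD61_N against SlanposCD61neg_N, 1347, 3802 and 4131 for Int against Slanneg_N, SlanposCD61_N and SlanposCD61neg_N, 53 and 129 for Slanneg_N against SlanposCD61_N and SlanposCD61neg_N, and 3363 for any difference. The 414 held SCART1 (-1.47, adjusted p = 0.00727), C1QA (1.46, adjusted p = 0.00759), CD63 (1.10, adjusted p = 0.00377) and ITGAM (1.06, adjusted p = 0.0135), so the 0 genes of that comparison belong to the unpaired edgeR fit. Under the block 293 of the fold changes of named genes kept their status, called or not, 40 gained a call and 0 lost it, and of the camera results 70 were the same. For Int against the nonclassical groups, interferon-stimulated genes gained a call (0.13, adjusted p = 0.0247), and NK cell markers (adjusted p = 0.274), complement (adjusted p = 0.0922) and mitochondrial genome transcripts (adjusted p = 0.0554) were not called. For Slanneg_N against the slan-positive groups nonclassical genes gained one (0.17, adjusted p = 0.0460), and between the CD61 groups chemoattractant receptors (0.24, adjusted p = 0.0288), scavenger and efferocytosis (0.26, adjusted p = 0.0473) and cytosolic ribosomal proteins (-0.07, adjusted p = 0.0288) did.

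The cause of the changes below was not tested. Leaving out the 4 libraries of highest olfactory receptor CPM, the background covariate and the length and GC offset were chosen after seeing the data. Of the camera results with a single library left out, 846 were the same, 51 stronger, 33 weaker and 6 reversed, and of the fold changes of named genes 3938 were the same, 11 stronger, 47 weaker and 0 reversed. With an estimated correlation 48 camera results were the same and 30 weaker. The list score of chemoattractant receptors was weaker with a prior count of 0.5 (exact adjusted p = 0.0517).

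Counts of genes passing are given with the edgeR count over all groups first. For Int against the nonclassical groups (2492), no low-count filter gave 1557, 2 surrogate variables 4022 and the length and GC offset 1200, and leaving out single libraries 1157 to 2944. For Slanneg_N against the slan-positive groups (0), DESeq2 gave 255, limma voom 9, thinned counts 1, 2 surrogate variables 224 and only the groups compared 2. For SlanposCD61_N against SlanposCD61neg_N (0), DESeq2 gave 2. For Int against Slanneg_N (456), DESeq2 gave 820, limma voom 742, 1 surrogate variable 808, 2 surrogate variables 1543, the covariate 832, the offset 259, omission of the 4 libraries 255, and single omissions 157 to 637. For Int against SlanposCD61_N (2052), no filter gave 1103, the offset 807 and single omissions 788 to 2055. For Int against SlanposCD61neg_N (2354), no filter gave 1303, 2 surrogate variables 4126, the offset 904 and single omissions 1063 to 2855. For Slanneg_N against SlanposCD61_N (0), DESeq2 gave 87, and against SlanposCD61neg_N (0), DESeq2 gave 112 and 2 surrogate variables 140. For any difference (1497), no filter gave 908, DESeq2 2545, limma voom 2482, 2 surrogate variables 2769, the covariate 2337, the offset 600, omission of the 4 libraries 820, and single omissions 624 to 1792. The 4 counts of 0 stayed at 0 in every single omission.

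Lists whose camera direction reversed are given by their median log2 fold change. Without Int replicate 1, NK cell markers stood at 0.230 between Int and the nonclassical groups (ranked lower), and without Int replicate 2, the highest, at 1.68. Without the 4 libraries, mitochondrial genome transcripts stood at 0.014 there (ranked lower), interferon-stimulated genes at -0.21 between Slanneg_N and the slan-positive groups and at 0.45 between the CD61 groups. With 2 surrogate variables, T cell markers stood at 0.24 in the former comparison and -0.60 in the latter. The rest lie between the CD61 groups, with the other end over single omissions in brackets. Without SlanposCD61_N replicate 1, nonclassical genes stood at -0.117 (up to 0.168). Without SlanposCD61_N replicate 3, T cell markers stood at -1.339 (up to 2.074), interferon-stimulated genes at 0.264 (down to -0.291), and a further list at 0.082 (down to -0.144). Without SlanposCD61neg_N replicate 3, T cell markers stood at -0.51.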

Other observations

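MALAT1, a nuclear RNA, made up 1.67 ± 0.29% of counts in Int, 2.58 ± 0.84% in Slanneg_N, 3.59 ± 0.62% in SlanposCD61_N and 3.65 ± 0.42% in SlanposCD61neg_N (SD, n = 3 each). Mitochondrial transcripts made up 7.32 ± 2.26%, 7.28 ± 2.22%, 5.65 ± 1.12% and 5.26 ± 0.96% in the same order (SD, n = 3 each). Trends with transcript length were taken on log2 CPM minus the mean of each gene over the 12 libraries. Such slopes balance over the libraries, so only their differences between groups can be read, not their signs. The slope per doubling of length was -0.10 ± 0.05 in Int (SD, n = 3) and 0.03 ± 0.08 in the nonclassical libraries (SD, n = 9; exact permutation p = 0.0455). It was -0.04 ± 0.08 in Slanneg_N (SD, n = 3) and 0.07 ± 0.07 in the slan-positive libraries (SD, n = 6; exact permutation p = 0.107). Across genes the Spearman correlation of fold change with length was -0.32 between Int and the nonclassical groups and -0.35 between Slanneg_N and the slan-positive groups. Over the 2191 genes called between Int and the other 9 libraries as 1 group, Slanneg_N was the highest nonclassical group in 1050 (79.7%) of the 1317 higher in Int and the lowest in 704 (80.5%) of the 874 lower in Int, where chance gives 33.3% on average. Genes do not vary independently, so 1 shared shift can set many of them, and these shares can lie far from that average by chance. Slanneg_N lay 0.291 log2 towards Int, and another choice of 3 nonclassical libraries 0.242.

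The platelet transcripts of SlanposCD61_N were weighed against 3 explanations, and the tests with the other platelet genes and with the correlation were chosen only after the result was seen. A higher ITGB3 transcript in the monocytes alone is argued against, since the other 25 platelet genes had a median log2 fold change of 1.94, with 24 positive. Background reads in 1 library remain open, since without SlanposCD61_N replicate 3, the smallest library, the list median was 0.90 with a lower quartile of 0.24. Platelets or platelet RNA carried with the cells may be the source: ITGB3 followed the mean of the other platelet genes over the 12 libraries centred on group means (Pearson r = 0.86, permutation p = 0.00025, adjusted p = 0.00025; 0.85 without SlanposCD61_N replicate 3). The permutation took the 12 centred values as independent. Centring ties the values of a group and libraries of one number may be related, so this p overstates the evidence. A sort on CD61 would itself keep cells with bound platelets, and ITGA2B, ITGB3, ITGB5 and SELP of the 26 genes also stand in other lists.

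The intermediate position of Slanneg_N was weighed next, and all tests but those of the position were chosen only after the result was seen. None of the 84 choices of 3 of the 9 nonclassical libraries other than Slanneg_N itself lay as far towards Int (0.29 log2 against at most 0.24; 1 of 84, one-sided exact p = 0.0119, the smallest possible). This argues against chance only if the 9 libraries are interchangeable, which the correlations by replicate number leave open. The position was 0.197 ± 0.062 after the length and GC offset and 0.202 without it, so such a trend as its whole source is argued against. That SD, over the left-out choices, holds no spread between Slanneg_N libraries. The number of small p-values between Slanneg_N and the slan-positive groups (1914) was reached in 12 of 84 choices with at most 3610, none of which took account of the replicate number, so chance cannot be excluded by them, while the 0 called genes are reached in 84 of 84 by construction and test nothing. The highest count, 1227, joined Slanneg_N replicate 2, SlanposCD61_N replicate 3 and SlanposCD61neg_N replicate 2, the nonclassical libraries of highest olfactory receptor CPM, which points to a structure of the samples. After the offset 1037 small p-values remained, reached in 27 of 84 choices with at most 5341, so a length and GC trend may account for part of them and remains open.

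For the genes called between Int and the nonclassical groups, the tests of length and background were chosen only after the result was seen, and the regroupings were redrawn after a first draw that had kept the real grouping in some. Regroupings that took no account of the replicate number gave fewer genes for Int against the nonclassical groups (2492, at most 1469 otherwise; 1 of 100). They also gave fewer for any difference (1497, at most 1383; 1 of 100). This argues against chance only if the libraries are interchangeable, which the correlations by replicate number leave open. With the offset, the 1200 genes between Int and the nonclassical groups were reached in 3 of 100, the real grouping included (at most 2066 otherwise). Chance is not excluded there. The highest other counts joined replicate 3 of Int, Slanneg_N and SlanposCD61_N (1469, and 1337 with the offset) or Slanneg_N replicate 2, SlanposCD61_N replicate 3 and SlanposCD61neg_N replicate 2 (2066), which points to a structure of the samples, in part by replicate number. For the length and GC trend the first criterion, a real count above all others under the offset, was not met and was replaced after this was seen, and by the replacement the trend as the whole cause is argued against, since fold changes kept a median 0.856 of their size (quartiles 0.682 and 1), yet it may carry part, since 1351 calls were lost as their median absolute log2 fold change went from 0.585 to 0.432 and their median SE from 0.141 to 0.193. Background in the 4 libraries as the whole cause is argued against in the same way, since 1601 of 2492 genes (64.2%) were still called without them.

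For pairs of groups 10 regroupings are too few for a share under 0.05. The real and highest other counts were 456 and 0 for Int against Slanneg_N (1 of 10), 2052 and 0 for Int against SlanposCD61_N (1 of 10), 2354 and 0 for Int against SlanposCD61neg_N (1 of 10), and 0 and 0 for the 3 pairs of nonclassical groups (10 of 10 each, by construction, which tests nothing).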
